A study of Mus musculus with 7 samples.

How the data were processed

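RNA of SCNT embryos was sequenced in 7 libraries, each from a pool of 50 to 100 embryos with an RNA integrity number above 7.0, per the labels' protocols. The labels of each library give the 2-cell stage; the treatment protocol, the same for all libraries, speaks of blastocysts too and does not say which embryos went into which library. The cDNA was made with a SMARTer Ultra Low Input kit and turned into libraries with a ScriptSeq v2 kit, per the labels. The deposited table holds 1 FPKM value (fragments per kilobase of transcript and per 1000000 mapped fragments) per gene and library, for 24319 rows and 7 libraries. The submitters' processing notes name STAR 2.5.2b, Cufflinks 2.2.1, Cuffnorm and R 3.3.2, with the mouse build mm9. Which tool made the table, which annotation was used, and whether the libraries were scaled to one another are not given in the sources used here. The table gives gene symbols without coordinates, so no positions are reported. Cufflinks shares fragments between near-identical genes by a model, so values of multigene families and of genes with many processed copies are uncertain.

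Groups were taken from the sample titles, which give each library a group and a replicate number. The labels speak of 2 to 3 biological replicates and do not say whether equal numbers in different groups mark a shared batch, oocyte donor or day. Embryos without melatonin are taken as untreated; a vehicle is named for the series and not for each sample. No 2 libraries held identical values.

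FPKM values were used as deposited, with no rescaling, as log2(FPKM + 1). Fold changes are on that scale, which understates the changes of low genes. A gene was tested if its FPKM was at least 1 in 2 or more libraries. The 1274 rows of small RNA genes and ribosomal RNA precursors were left out, and 12272 genes remained. Values of small RNA genes depend on a length below that of a sequenced fragment. Rn45s, the ribosomal RNA precursor, fell under the same rule, though that reason does not apply to it. Since the unit is not a count, limma 3.58.1 with an intensity trend was used in R 4.3.3, in 1 fit of all 7 libraries with the group as the only term (4 residual degrees of freedom). Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Errors of log2 fold changes are limma's standard errors (SE), and FPKM are given as mean ± SD. Further computing used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.

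The 32 gene lists were fixed before the data were examined, from general knowledge of embryos, apoptosis, cryopreservation stress and melatonin. They hold 1434 symbols, of which 1409 are in the table. Each list was tested against all other genes with camera in limma at a preset inter-gene correlation of 0.01, and again with a correlation estimated per list; adjusted p-values of lists are over the 32 lists of a comparison. Counts adjusted over the list alone use the members' limma p-values. The test weighs each gene by its spread, so its direction can differ in sign from the median and the mean of a list. That happened in 8, 10 and 5 lists of the comparisons CROC+K against FOC+K, CROC+K+M against CROC+K and CROC+K+M against FOC+K, none of which passed the test.

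The rule for named genes was also fixed beforehand. In each comparison it takes up to 10 rising and 10 falling genes past the threshold, filled up to 5 per direction with the smallest unadjusted p where fewer pass. It adds the 2 to 4 members with the smallest unadjusted p (4 in the pro-apoptotic and anti-apoptotic lists, 2 in the others) of each list that passes and of the lists for pro-apoptotic, anti-apoptotic, p53 target, antioxidant, transient 2-cell stage and cumulus cell marker genes, and Kdm4a in every library. Clone names and genes with a mean FPKM under 1 were left out, and 1 gene that the rule takes is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

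The tests were run on simulated libraries drawn from the means and spreads of the 12272 genes, with 200 genes changed. In the simulated comparison of CROC+K with FOC+K, 0 of 50 genes with a 2-fold change, 26 of 50 with a 4-fold, 41 of 50 with an 8-fold and 50 of 50 with a 32-fold change were recovered, beside 11 false calls. For CROC+K+M against CROC+K the numbers were 1, 22, 45 and 50 of 50, beside 14 false calls, and for CROC+K+M against FOC+K they were 0, 18, 46 and 50 of 50, beside 7. In each comparison 50 genes of each size were changed together, so the larger changes eased the adjusted threshold for the smaller ones. These shares overstate the recovery where few or no genes are called. Among measured genes Gtsf1l, with a log2 change of 3.77 ± 0.40 for CROC+K+M against CROC+K, had an adjusted p of 0.108 in limma. A list of oxidative phosphorylation genes shifted by 0.5 on the log2 scale in a simulated comparison of CROC+K with FOC+K was recovered at an adjusted p of 1.5e-08, and 0 of the 31 other lists were called. The simulation was built from means and spreads of single genes. In the measured libraries the estimated inter-gene correlation of this list was 0.67. The simulation thus gives no rate of false list calls where members vary together.

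The table holds no read totals. Low values of genes with 1 annotated transcript over 800 bases (3668 genes in the GENCODE M21 annotation, used for transcript lengths only) fell on steps. With a fragment length of 140 bases, which made the steps sharpest, 64.4% to 73.6% of the low values above the first step lay within 0.1 of a whole number of steps, where 20% would by chance. The first step is left out of this share, since the step was set at the most frequent low value. If a step is 1 fragment, FPKM were made with 4090000 to 6370000 fragments per library. A rescaling of libraries by the submitters would move these figures. Median ratio factors of the tested genes were 1.01 to 1.02, while FPKM sums ran from 552356 to 1017995. Factors this near 1 would follow from an earlier scaling by median ratios, so that alternative could move little. Counts were not recovered, since a gene with several transcripts has no single length.

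Alternatives covered the pseudocount, the filter on low values, quantile, sum and median ratio scaling, the small RNA rows, the samples in the fit, a replicate block, array weights, robust moderation, the list test's correlation and ranks, and leaving out each library in turn. A term for a library split seen in the data, a removal of a transcript length trend, and the estimated correlation together with that term or with 1 library left out were added after the data were examined. Where leaving out a library leaves a group with 1 library, that library is assumed to vary like the others.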

Results

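Gene expression was measured in mouse embryos made by somatic cell nuclear transfer (SCNT), in which the nucleus of a cumulus cell, a somatic cell that surrounds the oocyte, is placed in an oocyte stripped of its own chromosomes. All embryos had been injected with mRNA of Kdm4a, which encodes a histone demethylase. Each library is labelled as one of 2-cell embryos, while the treatment protocol given for all 7 libraries names embryos of the blastocyst stage as well. The recipient oocytes were fresh in the FOC+K group (2 libraries) and had been vitrified and warmed in the CROC+K group (3 libraries). The CROC+K+M group (2 libraries) came from vitrified and warmed oocytes as well, and its embryos were exposed to 10 µM melatonin, an indole hormone and antioxidant. Between 10496 and 11518 genes had an FPKM of at least 1 per library, and FPKM summed to between 552356 and 1017995. If a step of the low values is 1 fragment and the libraries were not rescaled, these values imply between 4090000 and 6370000 fragments per library. The 10 highest genes took 15.7% to 22.2% of the FPKM.

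Kdm4a was far from uniform within the groups. Its FPKM was 2014 and 816 in the FOC+K libraries, 497, 4051 and 4949 in CROC+K replicates 1 to 3, and 2797 and 689 in the CROC+K+M libraries, a 9.95-fold range from the lowest to the highest. The group means of 1415 ± 847 (SD, n = 2), 3166 ± 2354 (SD, n = 3) and 1743 ± 1491 (SD, n = 2) differed by less than this spread. The log2 fold change was 0.75 ± 1.06 (SE) for CROC+K against FOC+K, -0.63 ± 1.06 for CROC+K+M against CROC+K and 0.11 ± 1.16 for CROC+K+M against FOC+K, with adjusted p = 0.9996, 0.858 and 0.989 in limma.

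2 features set libraries apart in ways the groups do not fully explain. CROC+K+M replicate 1 had correlations of 0.851 to 0.875 with the other libraries over the tested genes, against 0.908 to 0.974 among the others. In it, Fabp3, a fatty acid binding protein gene, stood at an FPKM of 24404 against at most 4.36 elsewhere. The keratin genes Krt8 and Krt18 stood at 300.2 and 750.3 against at most 2.94 and 7.59, and Cdx2, a trophectoderm transcription factor gene, at 6.97 where all others are listed at 0. Rn45s, the ribosomal RNA precursor, was at 1183 and 1047 in FOC+K and 2114 in CROC+K replicate 1, and at 175.4 to 265.7 in the other 4 libraries. Apart from CROC+K replicate 1, this split follows fresh against vitrified oocytes. These genes were chosen after their values were seen.

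**Figure D1:**
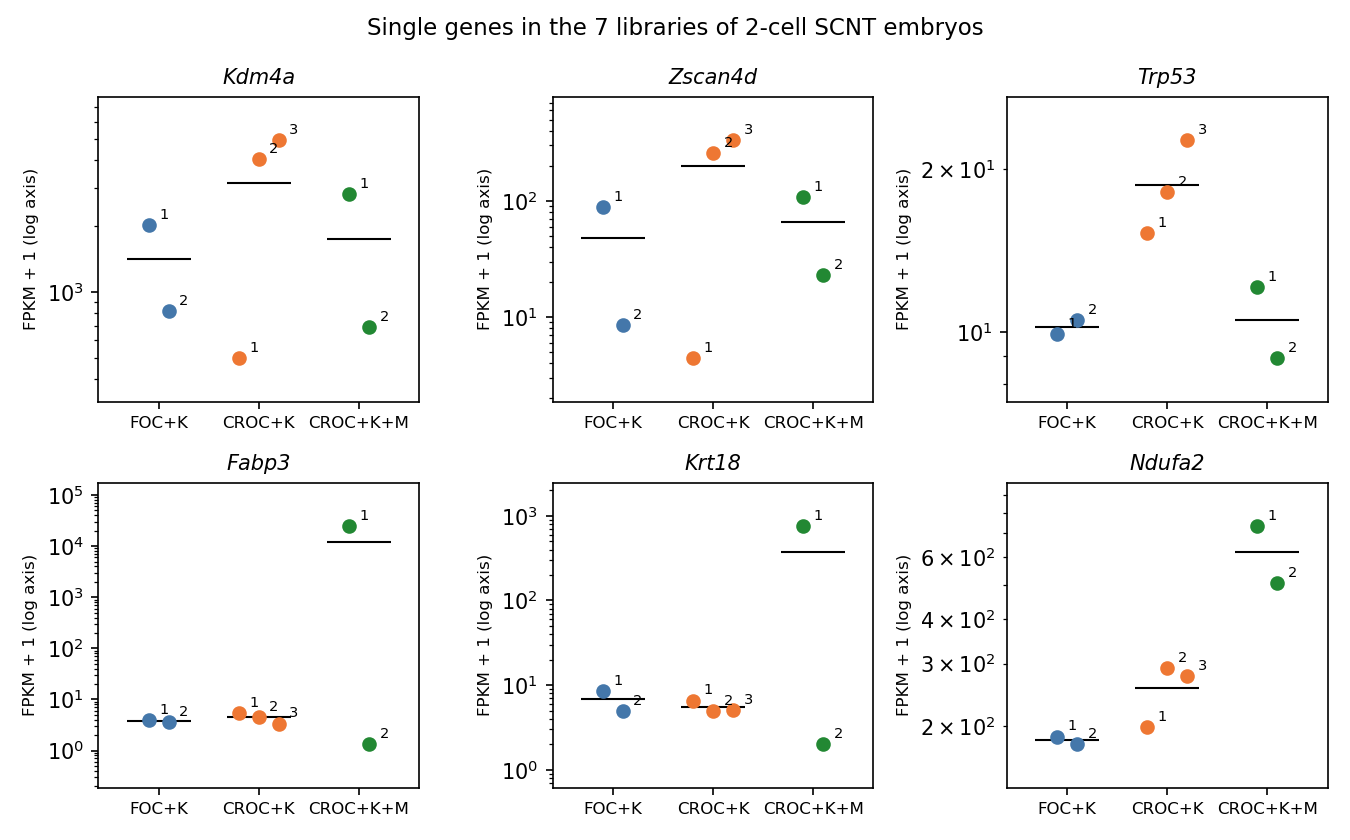
FPKM + 1 on a log axis for 6 genes in the 7 libraries; points are libraries with their replicate numbers, and horizontal lines are group means of FPKM + 1. Kdm4a and Zscan4d vary together within each group, Trp53 is highest in the 3 CROC+K libraries, and Fabp3 and Krt18 stand out in CROC+K+M replicate 1; Zscan4d, Fabp3 and Krt18 were chosen after their values were seen.

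The comparison of CROC+K with FOC+K asks what differs when the recipient oocyte has been cryopreserved. Among the pro-apoptotic genes, Pmaip1, which encodes the BH3-only protein Noxa, had a mean FPKM of 4.84 ± 1.60 (SD, n = 3) in CROC+K and 1.19 ± 1.0 (SD, n = 2) in FOC+K, a log2 fold change of 1.46 ± 0.47 (SE). Trp53, the gene of p53, was at 17.6 ± 3.72 against 9.21 ± 0.44, a change of 0.85 ± 0.31. Diablo, which encodes an antagonist of apoptosis inhibitors, was at 116.2 ± 13.5 against 76.8 ± 0.12, a change of 0.59 ± 0.24. Casp8, an initiator caspase gene, was at 7.08 ± 3.42 against 2.73 ± 1.0, a change of 1.05 ± 0.45. All 4 had an unadjusted p between 0.015 and 0.049, and an adjusted p of 0.9996, so none passed the threshold.

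The pro-apoptotic list as a whole had 22 of 41 measured genes with a higher mean in CROC+K and 19 with a lower one, a median log2 change of 0.03 and an adjusted p of 0.438 in the list test. In the anti-apoptotic list 17 of 31 genes had a higher mean, with a median of 0.11 and an adjusted p of 0.465. There the smallest unadjusted p was that of Pim3, a survival kinase gene, at 5.40 ± 3.62 against 12.8 ± 0.97 (log2 change -1.25 ± 0.45 SE). Naip1 (0.61 ± 0.34), Tnfaip8 (0.41 ± 0.26) and Aven (0.51 ± 0.34) had higher means in CROC+K; Naip1 has near-identical copies, so its level is uncertain. In both lists 0 genes passed when adjusted over the list alone. Within the 3 libraries with high Rn45s, where CROC+K has only replicate 1, the medians were 0.25 for the pro-apoptotic list, -0.0042 for the anti-apoptotic list and 0.36 for the p53 targets. Of the p53 targets, 19 of 29 had a higher mean (median 0.20, adjusted p = 0.135). Without CROC+K replicate 3 that list passed upward (adjusted p = 0.0170), and with an estimated correlation it did not (adjusted p = 0.972). Besides Pmaip1 they include Gadd45a, a stress response gene, at 83.4 ± 25.1 against 42.9 ± 0.77 (0.90 ± 0.36).

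2 of the 32 lists passed the list test for CROC+K against FOC+K. Ribosomal protein genes rose, with 65 of 81 higher, a median log2 change of 0.32 and an adjusted p of 0.00048, and maternal oocyte transcripts rose, with 46 of 63 higher, a median of 0.17 and an adjusted p of 0.0064. With an estimated correlation the adjusted p was 0.885 for both. No member of either passed over all genes or adjusted over the list alone. Examples among the ribosomal proteins are Rps27l (0.80 ± 0.32) and Rpl26 (2.55 ± 1.12), which is listed at 0.0016 and 0.0012 in FOC+K and 0.0015 in CROC+K replicate 3 and is uncertain because of its processed copies. Among the maternal transcripts they are Bpgm (0.70 ± 0.35) and Npm2, an oocyte nucleoplasmin gene (0.49 ± 0.24). Without FOC+K replicate 2 neither passed (adjusted p = 0.354 for ribosomal proteins and 0.102 for maternal oocyte transcripts). The ribosomal proteins also failed without CROC+K replicate 2 (0.179), and the maternal oocyte transcripts without CROC+K replicate 3 (0.175). Within the 3 libraries with high Rn45s, where CROC+K has only replicate 1, the medians were -0.07 for ribosomal proteins and 0.01 for maternal oocyte transcripts. With that library split as a term neither passed, and both tests pointed down (adjusted p = 0.215 for ribosomal proteins and 0.702 for maternal oocyte transcripts). After quantile normalization the tests pointed down as well, with adjusted p = 0.712 and 0.745. With equal FPKM sums the median of ribosomal proteins was -0.02 and that of maternal oocyte transcripts -0.17, while they lay 0.30 and 0.15 above the median of all genes.

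The transient 2-cell stage genes, a set switched on in the middle of this stage, had a median log2 change of 0.46 (27 of 36 higher, adjusted p = 0.0785) over all libraries, of 0.14 with equal FPKM sums (0.46 above that of all genes), and of -0.90 within the 3 libraries with high Rn45s. Without CROC+K replicate 1 the list passed upward (adjusted p = 2.3e-09), as it did without FOC+K replicate 1 (2.7e-08), and with the library split as a term, where CROC+K replicate 1 alone stands for CROC+K, it passed downward (5.7e-13). With an estimated correlation all 3 calls were lost, with adjusted p = 0.930, 0.809 and 0.817. Tdpoz2 (-1.79 ± 0.66) and Gm5662 (1.63 ± 1.02), both with close copies, had the smallest unadjusted p among its members. The antioxidant list had 28 of 49 genes higher, a median of 0.07 against a mean of -0.01, and an adjusted p of 0.843, with Prdx2 at 0.58 ± 0.30 and Oxr1 at -0.57 ± 0.33. Markers of the cumulus cell donor had 12 of 17 genes higher (median 0.09, adjusted p = 0.678), with Amhr2 at -0.54 ± 0.40 and Kctd14 at -0.65 ± 0.52.

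No gene of the 12272 passed the threshold in limma for CROC+K against FOC+K, nor with array weights or robust moderation. At an unadjusted p under 0.05 there were 269 genes, 140 higher and 129 lower, where 614 would be found by chance. With array weights there were 1744. These weights were estimated from the same libraries, at 2.57 for each FOC+K library and 0.42 for CROC+K replicate 1. The count with weights is thus no independent sign of a difference. In 2348 genes (19.1%) the libraries of the groups did not overlap, where chance gives 20%. Among the higher genes with the smallest p were Rpph1, the RNA of ribonuclease P (2.28 ± 0.55), Apoa2 (1.60 ± 0.40), Ccdc107 (1.83 ± 0.51) and Vgll4, a cofactor of TEAD transcription factors (1.55 ± 0.44). Among lower genes the smallest p belonged to Hspbp1, a co-chaperone gene (-1.80 ± 0.40), Gga1 (-1.12 ± 0.32), Slc4a11 (-1.69 ± 0.50), Fam209 (-1.75 ± 0.53) and Surf2 (-2.05 ± 0.62). Without CROC+K replicate 1 the number of genes at an unadjusted p under 0.05 was 1468, with 0 past the threshold and a smallest adjusted p of 0.055.

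The comparison of CROC+K+M with CROC+K asks what melatonin changes in embryos from cryopreserved oocytes. Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, rose. Of 76 measured genes 75 had a higher mean with melatonin, the median log2 change was 1.76, and the adjusted p in the list test was 9.3e-25. With an estimated correlation the adjusted p was 0.732. Adjusted over the list alone 14 of the 76 genes passed, all higher, and over all genes 0 did. Atp5k, an ATP synthase subunit gene, was at 1263 ± 682 (SD, n = 2) against 330 ± 111 (SD, n = 3), a log2 change of 1.87 ± 0.41 (SE). Ndufa2, a complex I subunit gene, was at 619 ± 160 against 254 ± 49.7, a change of 1.28 ± 0.29. Leaving out CROC+K+M replicate 1, the library with high Fabp3 and keratins, gave a median of 0.64, and the list still passed (adjusted p = 4.1e-08), though not with an estimated correlation (adjusted p = 0.208). With CROC+K+M replicate 2 left out instead, it passed with an estimated correlation, but that call rests on replicate 1 alone. There the list lay at a median of 2.41 above each gene's mean over the 7 libraries, against 0.19 in replicate 2. Within the 4 libraries with low Rn45s (2 of each group) its median was 1.81.

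Ribosomal protein genes (79 of 81 higher, median 0.82, adjusted p = 6.1e-13) and proteasome genes (40 of 46 higher, median 0.81, adjusted p = 9.5e-06) rose with melatonin when all libraries were used. With an estimated correlation the adjusted p was 0.732 for both. Neither passed without CROC+K+M replicate 1: the median was 0.17 with adjusted p = 0.0735 for ribosomal proteins, and 0.21 with adjusted p = 0.290 for the proteasome. Within the 4 libraries with low Rn45s the medians were 0.54 for ribosomal proteins, 0.83 for the proteasome and 0.28 for RNA splicing. After quantile normalization the medians were 0.46 for ribosomal proteins and 0.48 for the proteasome, and with a transcript length trend removed that of ribosomal proteins was 0.51. Examples are Rpl38 (1.99 ± 0.42, and 1.30 without CROC+K+M replicate 1), Rpl22 (1.26 ± 0.29), the proteasome activator gene Psme2 (1.44 ± 0.33) and Psmd14 (1.92 ± 0.48, and 1.14 without that library). RNA splicing genes rose, with 44 of 63 higher (median 0.35, adjusted p = 0.0013, and 0.708 as an adjusted p with an estimated correlation). Hnrnpm was at 24.2 ± 0.35 against 8.60 ± 0.64 (1.39 ± 0.27), and Lsm4 had a change of 1.54 ± 0.34. The splicing list passed without CROC+K+M replicate 1 (0.0174) and not without CROC+K replicate 1 (0.0567), after quantile normalization (0.0921) or with the library split as a term (0.0588). Its median was 0.09 after quantile normalization, 0.10 with equal FPKM sums (0.25 above that of all genes) and 0.08 with the length trend removed, where it passed (0.0168). In these 3 lists 0 genes passed when adjusted over the list alone.

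2 lists fell with melatonin. Maternal oocyte transcripts had a lower mean in 53 of 63 genes (median -0.40, adjusted p = 3.8e-09, and 0.708 as an adjusted p with an estimated correlation), with Zp2, a zona pellucida gene, at 11.5 ± 0.82 against 29.2 ± 3.41 (-1.27 ± 0.28) and Oas1e at 33.2 ± 5.44 against 66.8 ± 10.8 (-0.98 ± 0.28). The median was -0.36 without CROC+K+M replicate 1, where the list passed, -0.49 within the 4 libraries with low Rn45s, -0.61 after quantile normalization and -0.65 with equal FPKM sums. Transient 2-cell stage genes had a lower mean in 32 of 36 (median -0.75, adjusted p = 0.0012, and 0.732 as an adjusted p with an estimated correlation). Tdpoz4 had a change of -2.01 ± 0.52 and Pramel7 one of 1.14 ± 0.46, or 0.52 without CROC+K+M replicate 1. The 2-cell list did not pass without CROC+K replicate 3 (0.324) or without CROC+K+M replicate 2 (0.247). Its median was -1.31 without CROC+K+M replicate 1, and within the 4 libraries with low Rn45s it was -1.64. In each library this list lay in the order of Kdm4a within the groups. In both lists 0 genes passed when adjusted over the list alone.

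**Figure D2:**
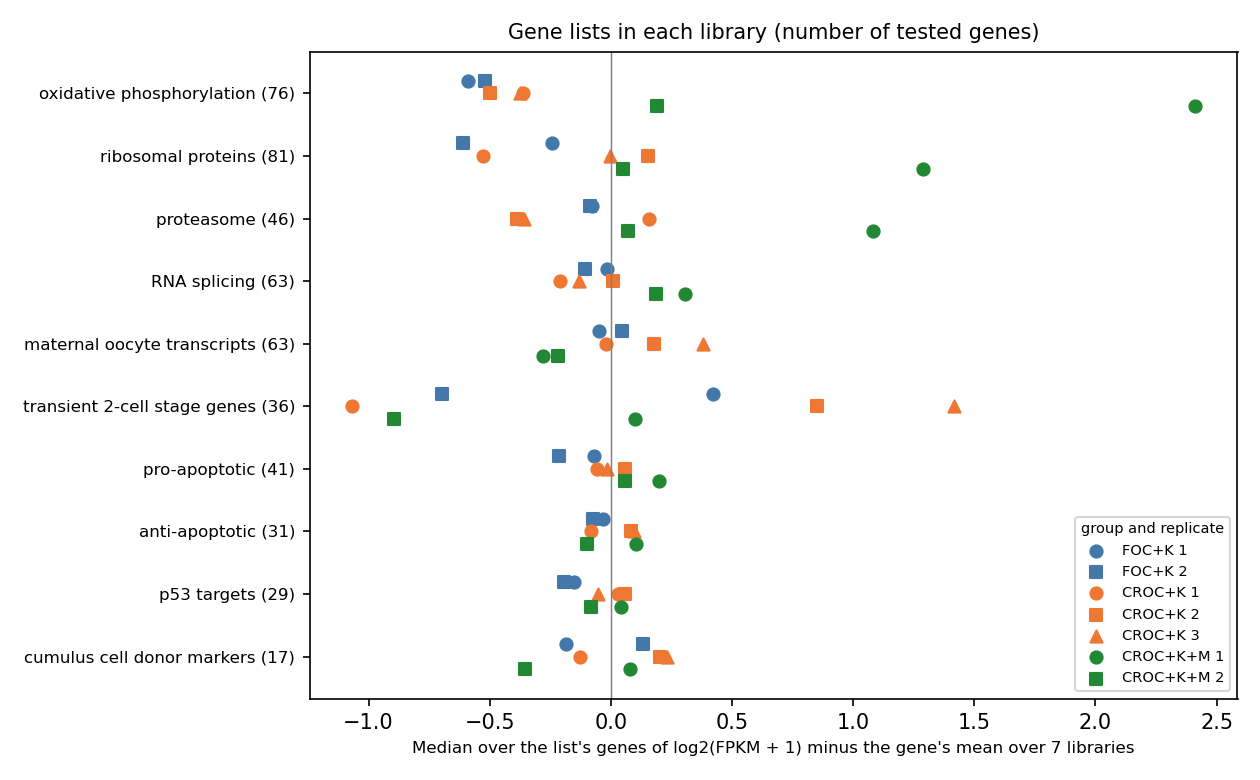
Median over a list's tested genes of log2(FPKM + 1) minus each gene's mean over the 7 libraries, for 10 lists; colours are groups, marker shapes are replicates, and numbers of tested genes are in brackets. The oxidative phosphorylation list lies at 2.41 and 0.19 in the CROC+K+M libraries and between -0.59 and -0.36 in the other 5, while the pro-apoptotic list lies between -0.21 and 0.20 and the anti-apoptotic list between -0.10 and 0.10 in all 7.

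The apoptosis lists did not pass with melatonin. In the pro-apoptotic list 26 of 41 genes had a higher mean in CROC+K+M than in CROC+K (median 0.32, adjusted p = 0.483), and the median was 0.08 without CROC+K+M replicate 1. Within the 4 libraries with low Rn45s the medians were 0.49 for the pro-apoptotic list, -0.07 for the anti-apoptotic list and 0.0031 for the p53 targets. Trp53 was at 9.51 ± 2.22 (SD, n = 2) in CROC+K+M against 17.6 ± 3.72 (SD, n = 3), a log2 change of -0.82 ± 0.31 (SE). Dapk2 had a change of -2.05 ± 0.66 and Dapk1, a related death-associated kinase gene, one of 1.08 ± 0.39. Pdcd6 had one of 2.52 ± 1.06, from an FPKM of 180.4 in CROC+K+M replicate 1 and 7.96 in replicate 2. In the anti-apoptotic list 17 of 31 had a higher mean, and the median (0.18) and mean (0.09) were above 0 while the test pointed down (adjusted p = 0.717), and the median was -0.07 without CROC+K+M replicate 1. Naip1 (-1.53 ± 0.34), Tnfaip8 (-0.73 ± 0.26), Dad1 (1.11 ± 0.47, and 0.38 without that library) and Bcl2l1, the gene of Bcl-xL (-0.77 ± 0.36), led it. For the p53 targets the median was -0.06, or -0.10 without that library, and the mean 0.09 (adjusted p = 0.609), with Gadd45b at 46.8 ± 6.78 against 100.5 ± 20 (-1.08 ± 0.27) and Cdkn1a, the gene of p21, at 43.3 ± 12.3 against 18.3 ± 5.91 (1.21 ± 0.34). In these 3 lists 0 genes passed when adjusted over the list alone.

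The antioxidant list had 36 of 49 genes higher with melatonin (median 0.38) and did not pass (adjusted p = 0.103), and its median was 0.01 without CROC+K+M replicate 1. It passed upward without CROC+K replicate 3 (adjusted p = 0.0483) and without CROC+K+M replicate 2 (adjusted p = 0.00246), and with an estimated correlation it did not (adjusted p = 0.865 and 0.290). Adjusted over the list alone 1 gene passed, Glrx3, a glutaredoxin gene, at 47.6 ± 17.4 against 12.4 ± 1.55 (1.82 ± 0.32, adjusted p = 0.0286 in the list). Gsta4, a glutathione transferase gene, had a change of 1.89 ± 0.58, or 1.23 without that library. Cumulus cell donor markers had a lower mean in 10 of 17 (median -0.34, adjusted p = 0.373, with a median of -0.56 without it), with Nppc at -1.78 ± 0.64 and Kctd14 at 0.93 ± 0.52.

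No single gene passed over all genes for CROC+K+M against CROC+K in limma, nor with array weights or robust moderation, where the smallest adjusted p was 0.108. At an unadjusted p under 0.05 there were 1281 genes, 821 higher and 460 lower, against 614 by chance, and the groups did not overlap in 2877 genes (23.4%, chance 20%). The smallest p among higher genes belonged to Snhg20, a small nucleolar RNA host gene (180.9 ± 26.5 against 33.5 ± 2.82, 2.40 ± 0.25), and Gtsf1l, a gametocyte-specific factor gene (41.5 ± 3.91 against 2.27 ± 1.33, 3.77 ± 0.40). Hspbp1 (2.76 ± 0.40), Sssca1 (2.54 ± 0.44) and H2-K1, a histocompatibility gene whose alleles vary between strains (1.91 ± 0.34), followed. Among lower genes it belonged to Tmem182 (-2.24 ± 0.39), Cep85l (-1.67 ± 0.30), Krt73 (-2.18 ± 0.42), Prlr, the prolactin receptor gene (-1.41 ± 0.28), and Tmem114 (-1.52 ± 0.32). With CROC+K+M replicate 2 left out, so that replicate 1 alone stands for melatonin, 635 genes passed, 625 of them higher.

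The comparison of CROC+K+M with FOC+K sets melatonin-treated embryos from cryopreserved oocytes beside embryos from fresh ones. Oxidative phosphorylation genes rose here too, with 76 of 76 higher, a median log2 change of 1.77 and an adjusted p of 2.5e-32 (0.647 as an adjusted p with an estimated correlation). Adjusted over the list alone 31 passed. Ndufa2 (1.75 ± 0.32) and Cox7a2, a cytochrome c oxidase subunit gene at 1470 ± 407 (SD, n = 2) against 444 ± 18 (SD, n = 2), a change of 1.70 ± 0.33 (SE), had the smallest p. Ribosomal proteins rose (80 of 81 higher, median 1.07, adjusted p = 1.3e-24, and 0.647 as an adjusted p with an estimated correlation), with Rpl38 at 2.23 ± 0.46 and Rpl26, listed near 0 in FOC+K, at 5.25 ± 1.22. Both passed without CROC+K+M replicate 1, with medians of 0.82 for oxidative phosphorylation and 0.36 for ribosomal proteins, and neither did so with an estimated correlation (adjusted p = 0.0857 and 0.962). Without CROC+K+M replicate 2, so that replicate 1 alone stands for melatonin, oxidative phosphorylation passed with an estimated correlation. RNA splicing genes rose (47 of 63 higher, median 0.33, adjusted p = 0.00057, and 0.636 as an adjusted p with an estimated correlation), with Snrpd2 (1.25 ± 0.30) and Lsm4 (1.44 ± 0.37), but not after quantile normalization (0.727) or with the library split as a term (0.397), and their median was 0.06 after quantile normalization and -0.18 with equal FPKM sums. Maternal oocyte transcripts fell (41 of 63 lower, median -0.22, adjusted p = 0.00049, and 0.647 as an adjusted p with an estimated correlation), with Zp2 (-1.08 ± 0.30) and Zbed3 (-1.02 ± 0.33). Their median was -0.67 after quantile normalization, -0.81 with equal FPKM sums (-0.35 relative to that of all genes) and -0.43 with the length trend removed. That of ribosomal proteins was 0.41, 0.48 (0.94 relative to that of all genes) and 0.70 under these settings. All FOC+K libraries have high Rn45s and all CROC+K+M libraries low Rn45s, so neither side of the split gives a value here. A fit with the split as a term rests on the CROC+K libraries, which lie on both sides. In it 7 lists passed: oxidative phosphorylation (adjusted p = 1.3e-15), the proteasome (1.2e-07), cholesterol and lipid metabolism (0.024) and ribosomal proteins (0.0275) upward, and transient 2-cell stage genes (2.1e-18), maternal oocyte transcripts (2.9e-08) and histone acetylation machinery (0.0211) downward. With an estimated correlation 0 lists passed in that fit (smallest adjusted p = 0.702).

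4 more lists passed upward for CROC+K+M against FOC+K with all libraries and did not without CROC+K+M replicate 1. They were the proteasome (43 of 46 higher, median 0.66, adjusted p = 5e-05, and 0.708 without that library), heat shock proteins and chaperones (33 of 43, 0.43, 0.0302, and 0.941), antioxidant defence (37 of 49, 0.46, 0.0302, and 0.941) and spindle and cytoskeleton (38 of 49, 0.46, 0.0302, and 0.178). Without that library the medians were 0.12, -0.03, 0.06 and -0.17. With an estimated correlation the adjusted p was 0.725 for the first 3 and 0.746 for spindle and cytoskeleton. Without FOC+K replicate 2 the adjusted p was 0.258 for heat shock proteins and chaperones and 0.0846 for both antioxidant defence and spindle and cytoskeleton. The latter 2 also failed without CROC+K replicate 1 (0.0523 and 0.112), and spindle and cytoskeleton without CROC+K replicate 2 (0.0575). After quantile normalization these 4 had medians of 0.20, 0.09, 0.16 and 0.32 and adjusted p of 0.066, 0.497, 0.334 and 0.200. With the length trend removed the medians were 0.44, 0.20, 0.26 and 0.23, and antioxidant defence did not pass (adjusted p = 0.0588). Among genes with an FPKM of at least 5, and with the library split as a term, only the proteasome passed. With equal FPKM sums the medians of proteasome, heat shock, antioxidant and spindle genes were 0.07, -0.14, -0.08 and -0.06. Their leading members were Psmd14 (1.52 ± 0.52), Psmb2 (1.21 ± 0.43), Cct7 (1.09 ± 0.37), Hspe1 (0.83 ± 0.36), Glrx3 (1.57 ± 0.35), Park7 (1.65 ± 0.52), Tubb2a (-1.21 ± 0.37) and Cttn (1.33 ± 0.49). Without CROC+K+M replicate 1 the change was 0.74 for Psmd14, 0.65 for Psmb2, 0.62 for Cct7, 0.41 for Hspe1, 0.85 for Park7 and 0.68 for Cttn. In these lists and those for ribosomal proteins, splicing and maternal transcripts 0 genes passed when adjusted over the list alone.

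The apoptosis lists did not pass for CROC+K+M against FOC+K either. The pro-apoptotic list had 29 of 41 genes higher (median 0.31, adjusted p = 0.121, and 0.0463 without CROC+K+M replicate 2, where the adjusted p was 0.287 with an estimated correlation). Without CROC+K+M replicate 1 its median was 0.17 (adjusted p = 0.941). Its leading members were Cycs, the cytochrome c gene, at 1.52 ± 0.39, Diablo at 0.61 ± 0.26, Pdcd5 at 1.76 ± 0.83 and Pdcd6 at 2.45 ± 1.16. Cycs also stands in the oxidative phosphorylation list. Without that library Cycs was at 1.01, Pdcd5 at 0.30 and Pdcd6 at 0.28. The anti-apoptotic list had 17 of 31 higher (median 0.03, or -0.05 without that library, adjusted p = 0.955), with Dad1 (1.43 ± 0.51, and 0.70 without it), Naip1 (-0.93 ± 0.37), Bcl2l12 (1.27 ± 0.56) and Birc5, the survivin gene (0.55 ± 0.29, and -0.10 relative to the median of all genes after quantile normalization and 0.42 relative to it with equal FPKM sums). For the p53 targets the median was 0.32 (adjusted p = 0.476), and without CROC+K+M replicate 1 it was 0.06 while the test pointed down. Perp had a change of 2.63 ± 1.39, from an FPKM of 38.5 in CROC+K+M replicate 1 and 0.45 in replicate 2, and Gadd45g one of 1.5 ± 0.88. Transient 2-cell stage genes had a median of -0.08 (adjusted p = 0.150), with Tdpoz4 (-2.16 ± 0.57) and Tdpoz2 (-1.80 ± 0.72). The list passed downward without CROC+K+M replicate 1 (0.0084, median -0.57) and without FOC+K replicate 2 (4.4e-05), and with an estimated correlation it did not (adjusted p = 0.962 and 0.781). Cumulus cell donor markers had a median of -0.09 (adjusted p = 0.611), or -0.36 without CROC+K+M replicate 1, with Nppc (-1.87 ± 0.70) and Gja1 (1.23 ± 0.72, and 0.37 without that library).

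No single gene passed in limma for CROC+K+M against FOC+K, nor with array weights or robust moderation (smallest adjusted p = 0.508, with array weights). At an unadjusted p under 0.05 there were 793 genes, 547 higher and 246 lower, against 614 by chance. The 2 groups did not overlap in 5034 genes (41.0%), where chance gives 33.3%. Snhg20 (1.97 ± 0.27), the histone gene H2afj (2.06 ± 0.36), Gtsf1l (2.49 ± 0.43), Tma7 (2.21 ± 0.40) and the copper chaperone gene Atox1 (1.72 ± 0.31) had the smallest p among higher genes. Slc39a8, a metal transporter gene (-2.17 ± 0.48), Tuba3a, a tubulin gene with a near-identical copy (-1.46 ± 0.32), Il31 (-1.73 ± 0.39), Rnf126 (-1.29 ± 0.30) and Mansc1 (-1.32 ± 0.32) had it among lower genes. When CROC+K+M replicate 2 was left out, 529 genes passed, 524 of them higher.

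Whether melatonin moved genes against the direction of cryopreservation was asked across genes, which are not independent replicates. The log2 change of CROC+K+M against CROC+K had a Pearson correlation of -0.40 and a Spearman correlation of -0.40 with that of CROC+K against FOC+K over 12272 genes, and 64.2% of genes had opposite signs. The CROC+K libraries stand in both changes with opposite sign, and 100 simulated sets of libraries with no group effect gave a mean Pearson correlation of -0.40 (range -0.42 to -0.37), a mean Spearman correlation of -0.37 (range -0.3959 to -0.3547, with -0.3961 observed) and 63.0% opposite signs (range 62.0% to 64.0%). The covariance was -0.131, against -0.102 in the simulated sets (range -0.111 to -0.0929), a difference of -0.0286. The Spearman correlation, the share of opposite signs and the covariance thus lay outside their simulated ranges and the Pearson correlation within its own. With a library left out the excess of the covariance stayed in 4 cases and turned in 3. It stayed without CROC+K replicate 1 (-0.351 against a simulated -0.130), FOC+K replicate 1 (-0.161 against -0.122), CROC+K+M replicate 1 (-0.155 against -0.0755) and CROC+K+M replicate 2 (-0.109 against -0.0759). It turned without FOC+K replicate 2 (-0.101 against -0.121), CROC+K replicate 2 (-0.120 against -0.156) and CROC+K replicate 3 (-0.119 against -0.152). The Pearson correlation was -0.49 without CROC+K+M replicate 1, below its simulated range of -0.35 to -0.29, and lay below its range without FOC+K replicate 1 (-0.41) and CROC+K replicate 1 (-0.62) too. It lay above its range without CROC+K replicate 2 (-0.38), CROC+K replicate 3 (-0.38) and CROC+K+M replicate 2 (-0.21). The simulated genes varied independently of one another, so the ranges leave out variation that genes share. With 3 CROC+K libraries they could not be split into sets of 2 each, so part of the excess may come from these shared libraries. With the library split by Rn45s as a term the correlation was 0.20, against a mean of -0.0024 (range -0.04 to 0.04) in simulated sets. In that fit CROC+K replicate 1 gives the first change and CROC+K replicates 2 and 3 give the other, so the 2 changes share 0 libraries and the value is not comparable with the -0.40.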

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

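Both values were picked out after the data had been seen. They lie in rows left out of the comparisons, which were tested only when the small RNA rows were kept.

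Rn45s, the ribosomal RNA precursor, reached an FPKM of 2114 in CROC+K replicate 1, above the 1183 and 1047 of the fresh-oocyte controls. The other 4 libraries from vitrified oocytes lay between 175.4 and 265.7.

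Snora47, a small nucleolar RNA, is listed at 0 in both fresh-oocyte controls and between 48.1 and 158.6 in the 5 libraries from vitrified oocytes, with 158.6 in CROC+K replicate 3. It was left out of the tests as a small RNA row and was the gene called when those rows were kept; its FPKM depends on a length below that of a fragment.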

How the results depend on the processing

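The term for the Rn45s library split, the length trend, and the estimated correlation with a library left out or with the split were added after the data were seen. The 3 counts of changed genes were 0 in 53 of 57 alternatives. Keeping the small RNA rows gave 1 gene, Snora47, higher in CROC+K and in CROC+K+M than in FOC+K. Leaving out 1 library gave 0 to 0 genes for CROC+K against FOC+K, 0 to 635 for CROC+K+M against CROC+K and 0 to 529 for CROC+K+M against FOC+K, with both highest values from CROC+K+M replicate 1 as the lone treated library. Without CROC+K replicate 1 the smallest adjusted p was 0.055 and 0.052 for the first 2 comparisons.

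The counts of lists that passed (2, 6 and 8 in these comparisons) were 0, 0 and 0 with an estimated correlation. With that correlation and the split as a term or 1 library left out they were 0 as well, except 1 in each melatonin comparison without CROC+K+M replicate 2. In those fits replicate 1 alone stands for melatonin, and oxidative phosphorylation passed upward. After quantile normalization they were 0, 5 and 4, with 2 of the last 4 down, against 1 of the 8 without it. With an FPKM of at least 5 in 2 libraries the last was 5. With the library split as a term the first was 6, 3 of them down. With the length trend removed they were 2, 6 and 7, without antioxidant defence (adjusted p = 0.0588) in the last. Leaving out 1 library gave 0 to 4, 4 to 13 and 6 to 12. The causes were not tested, except that the stricter filter tested fewer genes. Quantile normalization moved the median log2 change of ribosomal proteins for CROC+K against FOC+K from 0.32 to 0.02. Equal FPKM sums moved the median of all genes to -0.32, -0.15 and -0.46; relative to it, oxidative phosphorylation stayed at 0.11, 1.66 and 1.64. For CROC+K+M against FOC+K the medians of splicing, antioxidant, heat shock and spindle genes turned negative with equal sums, while staying above that of all genes.

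The replicate block gave 0 changed genes in each comparison and 1 list instead of 2 for CROC+K against FOC+K, where maternal oocyte transcripts were at an adjusted p of 0.205. For CROC+K+M against CROC+K it gave 6 lists, with antioxidant defence (0.0325) in and transient 2-cell stage genes (0.337) out, and for CROC+K+M against FOC+K it gave 8. Deviations of same-numbered libraries correlated at -0.46, -0.27, -0.03, 0.03 and, for FOC+K with CROC+K+M, -0.01. In a group of 2 libraries the deviations are mirror images, so each value forces its opposite. These values can neither show nor exclude a shared batch, oocyte donor or day.

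The relation of the melatonin change to the cryopreservation change was 0.20 with the split as a term, where the changes share 0 libraries, and -0.62 (without CROC+K replicate 1) to -0.21 (without CROC+K+M replicate 2) with a library left out, where simulated sets gave -0.50 and -0.32; without CROC+K+M replicate 1 it was -0.49 against -0.32. Of 2035 alternatives for 108 single-gene changes, 1994 kept direction and side, 30 passed the threshold, all of them without CROC+K+M replicate 2, and 11 reversed. For CROC+K+M against FOC+K, Birc5 was -0.18 after quantile normalization and -0.049 with equal sums (-0.10 and 0.42 relative to all genes), Gja1 was -0.27 with the split, and Kdm4a was -0.63, -0.48 (-0.54 and -0.018 relative to all genes) and -3.05 under these settings and -0.90 to 1.12 with a library left out. With the split, Gm5662 was -0.47 and Kdm4a -1.36 for CROC+K against FOC+K. Kdm4a ranged from -1.69 to 0.38 for CROC+K+M against CROC+K with a library left out. The cause was not tested. The 1994 alternatives that kept direction and side carry little weight. No gene passed with all libraries, so none could fall below the threshold. Some settings leave the log2 change as it is, such as robust moderation or leaving out a library outside the comparison. Most of these genes were also named for a small p in the same data. At this depth and number of libraries, simulated 2-fold changes were recovered in 0 or 1 of 50 genes.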

Other observations

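Of the tests below, those of scaling with equal FPKM sums, of the Kdm4a order, of collection stage and of ribosomal proteins without 1 library were chosen only after the result was seen. The scaling test stands in for one chosen beforehand, median ratio scaling, whose factors of 1.01 to 1.02 moved nothing. 2 further tests, of blastocysts alone under the name of CROC+K+M replicate 1 and of depth for the Kdm4a pattern, were run and are left out here.

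Gene groups not described so far did not pass in any comparison with all libraries, the group as the only term, deposited FPKM and the preset correlation without ranks. For CROC+K against FOC+K, preimplantation lineage and pluripotency genes had 20 of 27 means lower (median log2 change -0.16, adjusted p = 0.135) and unfolded protein response genes 24 of 37 higher (0.09, adjusted p = 0.135). For CROC+K+M against CROC+K, cholesterol and lipid metabolism genes had 29 of 41 higher (0.41, adjusted p = 0.103), autophagy and lysosome genes 32 of 49 higher (0.33, adjusted p = 0.171), circadian clock genes 15 of 19 lower (-0.30, adjusted p = 0.103), innate immune and interferon genes 18 of 25 lower (-0.23, adjusted p = 0.115) and DNA methylation machinery 11 of 17 lower (-0.20, adjusted p = 0.103). Melatonin receptor and synthesis genes had 5 of 10 higher (0.01, adjusted p = 0.717) and H3K9 methylation and heterochromatin genes 16 of 36 higher (-0.05, adjusted p = 0.380). Without CROC+K+M replicate 1 the medians for CROC+K+M against CROC+K were 0.07 for cholesterol and lipid metabolism, 0.12 for autophagy and lysosome, -0.19 for the circadian clock, 0.05 for innate immune and interferon genes, -0.0053 for DNA methylation machinery, -0.17 for melatonin receptors and synthesis and 0.06 for H3K9 methylation. With all libraries, the group as the only term, deposited FPKM and the preset correlation without ranks, 23 of the 32 lists passed in none of the 3 comparisons. With 1 library left out some of them did, and none of those with an estimated correlation. Ribosome biogenesis passed upward for CROC+K+M against FOC+K without CROC+K+M replicate 1 (median 0.25 against 0.03 with all libraries, adjusted p = 0.0311, and 0.962 with an estimated correlation). In the same comparison without FOC+K replicate 2, histone acetylation machinery (adjusted p = 0.0436) and cell cycle and mitosis (0.0456) passed downward. For CROC+K+M against CROC+K, circadian clock genes passed downward without CROC+K replicate 3 (0.0483), and without CROC+K replicate 2 innate immune and interferon genes passed downward (0.0309) and preimplantation lineage and pluripotency genes upward (0.0344; 0.045 downward for CROC+K against FOC+K). With CROC+K+M replicate 2 left out, so that replicate 1 alone stands for melatonin, cholesterol and lipid metabolism (0.017), autophagy and lysosome (0.0434) and preimplantation lineage and pluripotency genes (0.017) passed upward and innate immune and interferon genes (0.0446) and cell cycle and mitosis (0.0106) downward against CROC+K. Against FOC+K, cholesterol and lipid metabolism (0.0198) and autophagy and lysosome (0.0463) then passed upward and cell cycle and mitosis (0.0206) downward. Of lists that passed in another comparison with all libraries, heat shock proteins and chaperones passed upward for CROC+K against FOC+K without FOC+K replicate 1 (0.0200) and oxidative phosphorylation without CROC+K+M replicate 1 (0.0286) or 2 (0.0331), and for CROC+K+M against CROC+K without CROC+K+M replicate 2 heat shock proteins and chaperones (0.0120) and spindle and cytoskeleton (6.1e-08) passed upward. These 5 calls were not kept with an estimated correlation either (adjusted p of 0.290 to 0.831).

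The transient 2-cell stage genes followed Kdm4a over the 7 libraries. Zscan4d, the best known of them and one of a family of near-identical copies, had an FPKM of 86.9 and 7.56 in FOC+K, 3.44, 257.4 and 332.2 in CROC+K replicates 1 to 3, and 107.1 and 21.9 in CROC+K+M. On the log2 scale the mean of the list had a Pearson r of 0.98 with Kdm4a (exact permutation p = 0.0006, adjusted p = 0.019 over 32 lists) and a Spearman rho of 0.96 (exact permutation p = 0.0028, adjusted p = 0.089); without CROC+K replicate 1 and CROC+K+M replicate 2, the farthest from the median Kdm4a, r was 0.95. None of the other 31 lists passed for either coefficient. DNA damage response and repair came next with an r of -0.91 (exact permutation p = 0.0036, adjusted p = 0.057). These permutations treat the 7 libraries as interchangeable, though they come from different groups and different sides of the Rn45s split. The p-values thus do not allow for the design. Within groups only 24 orders exist, so a one-sided exact p cannot fall under 0.042, before any adjustment over lists.

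This pattern was weighed against 3 explanations. Scaling between libraries of the size given by equal FPKM sums is argued against by the ranges alone. Its factors were 0.76 to 1.41, while Kdm4a spans a 9.95-fold and Zscan4d a 96.6-fold range. With these factors rho was 0.96, but factors so small could hardly have lowered it, so this rho decides nothing. The amount of injected Kdm4a mRNA left in the embryos stays open: the libraries had the same order by Kdm4a and by the list in every group (one-sided exact p = 0.042 over 24 within-group orders), but this order restates the relation it was found from and decides nothing. The stage at which embryos were collected cannot be told apart from it: maternal oocyte transcripts had a rho of 0.61 with Kdm4a, between the bounds set, and the labels give no collection times.

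CROC+K+M replicate 1 held transcripts that were nearly missing elsewhere or far lower. Lgals1 stood at 5904 against at most 103.5 in the other libraries, S100a11 at 3075 against 34.7, Tspan8 at 1250 against 6.17, Dppa1 at 1060 against 7.99, Wfdc2 at 412 against 0.83, and Dppa5a at 19491 against 1198; Dppa5a was chosen after its values were seen. Cldn6, Upp1, Tdgf1 and Fgf4, 4 of the 24 genes listed as blastocyst genes before their values were seen, were not above the highest other library. Of the 24, 16 had a mean FPKM of at least 1 in the other 6 libraries and 5 stand in other lists.

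For this library 3 explanations were weighed. In CROC+K+M replicate 2, 0 of the 24 genes were 2-fold above the untreated libraries, which argues against an effect shared by melatonin-treated embryos. As a hypothesis, RNA of blastocysts is a candidate source: 14 of the 24 lay 4-fold or more above the highest other library, which is also consistent with RNA of other epithelial or pluripotent cells, and the treatment protocol in the labels names blastocysts beside 2-cell embryos. Cumulus cells cannot be told apart from it. Of 44 cumulus cell donor markers, 17 had an FPKM of at least 1 in 2 or more libraries and entered. A marker present in this library alone was thus left out. The markers that entered differed by a median of 0.0904 from the mean of the other libraries. That median lay under the bound set beforehand to argue against cumulus cells. Members went both ways (quartiles -0.47 and 0.87), with the upper quartile above that bound. The condition on quartiles was added only after the result was seen.

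The rise of oxidative phosphorylation genes with melatonin was weighed against transcript length and that library. These genes are short (median 650.5 bases against 1437 for all genes), and changes across genes ran against length (Spearman rho -0.16 over genes, which are not independent replicates); with the length trend removed the median log2 change was 1.39 (adjusted p = 2.8e-26), which argues against length as the whole cause. CROC+K+M replicate 1 alone cannot be told apart from melatonin. Without that library the median was 0.64, above the bound of 0.5 set for an effect beyond it. The standard error between libraries, 0.088, holds no spread of treated libraries, since only 1 was left. The CROC+K+M libraries themselves lay at list medians of 2.41 and 0.19 above each gene's mean. That bound did not allow for a single remaining treated library, whose own deviation cannot be separated from melatonin. For ribosomal proteins the median was 0.17 without it, with a standard error between libraries of 0.41 that spans both bounds. An effect of melatonin stays among the open explanations.

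CROC+K replicate 1 correlated with FOC+K replicate 2 at 0.974, as FOC+K replicates 1 and 2 did with each other, and at 0.912 and 0.908 with the other CROC+K libraries.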
